A study of Homo sapiens with 4 samples.

How the data were processed

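RNA sequencing was done on 4 libraries of the human keratinocyte line HaCaT, 1 for each combination of siRNA (siControl or siSIRT7) and X-ray treatment (none or 8 Gy). Total RNA was extracted, treated with DNase I and made into Illumina libraries. The time between irradiation and harvest, the siRNA sequence, the way rRNA was avoided and the strandedness of counting are not given in the sources used here.

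The authors' table held 44591 entries, each with a deposited raw count and a deposited TPM value for every library. The counts were whole numbers with no normalization. The TPM values were made by the authors from those counts and a deposited gene length in bases (unit: other, a property of the gene), and TPM recomputed from counts and length differed from the deposited TPM by at most 4.2e-06. The processing notes name HISAT2, TopHat2, Bowtie2 and HISAT with the hg19 build, without versions and without saying what each did. Every measured column could be tied to a library by its label. In the table, 27 gene names had the form of a date, and 2 names occurred on more than 1 entry, 4 entries in all. Coordinates are those of the deposited table (hg19).

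Library totals were 19745170 counts for unirradiated siControl, 16829544 for unirradiated siSIRT7, 19698978 for irradiated siControl and 17654039 for irradiated siSIRT7. A library of that depth gives narrow counting intervals for abundant genes and wide ones near the floor. Intervals are exact conditional binomial intervals at 95% for the ratio of the counts of a pair of libraries. A zero count was set to a floor of 3 counts when a bound on a fold was computed. The intervals cover counting error alone and the floor only that of the library at zero. Neither covers the variation between cultures, since each condition has 1 library.

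Counts were scaled to CPM with TMM library sizes in edgeR 4.0.16 under R 4.3.3. TMM factors were 1.01688, 0.992725, 0.998623 and 0.991968 in the order of the totals above. Log2 ratios used a prior count of 2, and a gene was eligible when it reached 5 CPM in at least 1 library of the comparison. Each pair of libraries was described by the number of genes that differed by 2-fold or more, with no p-value. The additive test was an edgeR quasi-likelihood model with a term for the siRNA and a term for irradiation over 11129 genes, with Benjamini-Hochberg adjustment at 0.05. That model has 1 residual degree of freedom. It gave no gene a spread of its own and took one pooled over all 11129 genes with a trend on abundance (infinite prior degrees of freedom). The common dispersion was 0.00614. The model counts any departure from additivity as error. In the text, rose and fell are used for genes that passed it, and higher and lower for values without a test. Its p-values describe these 4 libraries and take the fitted spread for that between cultures, which was not measured.

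Agreement between pairs of libraries that share no library was measured across genes by Pearson's r and Spearman's rho. Genes are not independent replicates, so no p-value is given. For each of 25 gene lists, the median log2 ratio of the measured members was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. Such a percentile is a description of these libraries and no test between conditions. List members were also counted by the additive test, adjusted over all genes and adjusted over the list alone. Several lists share members.

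The comparisons, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The rule named SIRT7; the 12 genes with the largest and the 12 with the smallest change common to both pairs, for the knockdown and for irradiation; the 3 highest and 3 lowest genes of each pair; and the 6 highest and 6 lowest differences of the irradiation effect. It also named 2 to 4 members of each list. Entries without a gene symbol were passed over, and 1 gene the rule took was left out of the text. Further members and genes are named where they passed the additive test, and these were chosen after their values were seen.

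Alternatives were prior counts of 0.5 and 10, floors of 1 and 20 CPM and no floor, median-of-ratios scaling, log2(TPM + 1), the filterByExpr minimum of edgeR, DESeq2 1.42.0 and limma-voom (limma 3.58.1). Its filter on mean counts left DESeq2 without an adjusted p for 1942 of the 11129 genes in the knockdown test and for 0 in that of irradiation, so a gene that DESeq2 did not call for the knockdown may not have been judged. Chosen after seeing the data were removal of a cubic trend of each library on transcript GC content and gene length, restriction to protein-coding genes, and floors of 1 and 20 CPM in the additive test. The GC trend used transcript sequences of GENCODE release annotation matched by symbol, which covered 92.1% of the tested genes. For 3' UTR searches, the UTR was taken from the longest coding transcript of each symbol, and 10096 of 10443 eligible protein-coding genes had a UTR of at least 50 bases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

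The procedures were tested on simulated data. With 200 planted changes, the additive test recovered 95% of 2-fold and 71% of 1.5-fold knockdown changes and 97% and 77% of irradiation changes, with 2 false calls for each. Those counts were drawn with the spread fitted to the real libraries and with additive changes alone. The rates therefore cover neither variation between cultures, nor departures in 1 library, nor trends on GC content. Of 40 unchanged lists, 1 fell outside the central 95% of the random lists, and 20 of 20 lists shifted by 0.3 fell in the upper tail. The UTR search ranked a planted heptamer first in 20 of 20 trials with a shift of -0.15.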

Results

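The series asked how lowering SIRT7, a nuclear NAD-dependent deacylase, changes the RNA of HaCaT keratinocytes with and without ionizing radiation. HaCaT is a spontaneously immortalized human skin keratinocyte line. The 4 libraries form 4 groups of 1: unirradiated siControl, unirradiated siSIRT7, irradiated siControl and irradiated siSIRT7, the irradiated cells having received 8 Gy. Totals ran from 16829544 to 19745170 counts, and between 22013 and 23131 genes had a count in a library. No group has replicates, so each value below is that of 1 library and errors are counting intervals or come from the additive model.

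SIRT7 (chromosome 17, 79869815 to 79876058, hg19) was lower in both siSIRT7 libraries. Its level was 62.0 CPM with siControl and 21.7 CPM with siSIRT7 in unirradiated cells, and 64.8 and 20.7 CPM in irradiated cells. The log2 ratios were -1.51 (95% counting interval -1.69 to -1.34) and -1.64 (-1.82 to -1.48). In the additive model SIRT7 fell by 1.58 on the log2 scale (SE 0.124, adjusted p = 9.4e-34), and no other member of the list of sirtuin genes, 6 of them measured, passed the test for the knockdown (1 adjusted over the list alone, SIRT7). Irradiation ratios of SIRT7 were 0.06 with siControl and -0.07 with siSIRT7.

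**Figure D1:**
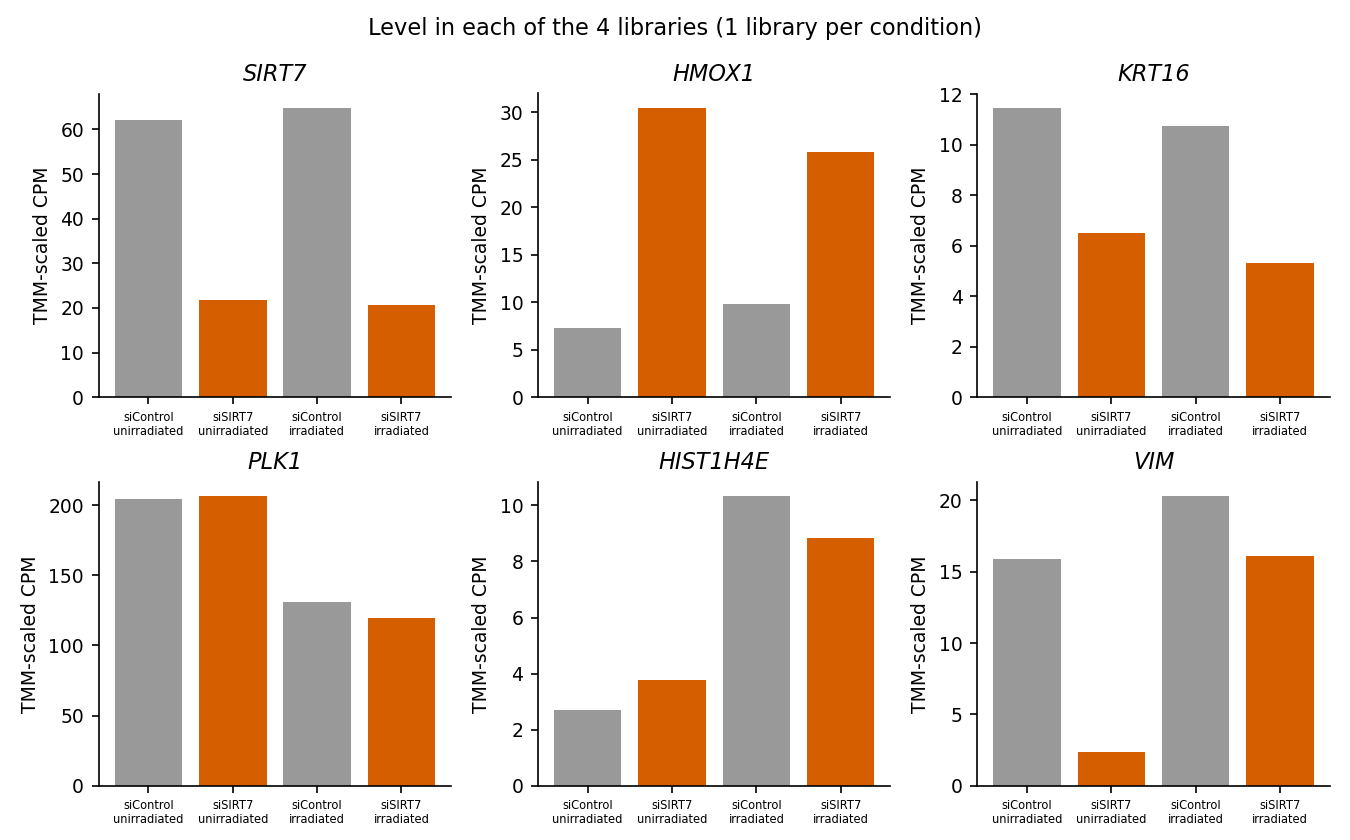
Bars give the TMM-scaled CPM (y axis, from 0) of 6 genes in each of the 4 libraries, grey for siControl and orange for siSIRT7. SIRT7 stands at 62.0 and 64.8 CPM with siControl against 21.7 and 20.7 CPM with siSIRT7, while VIM is low in the unirradiated siSIRT7 library, at 2.33 CPM.

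The first question was which other genes differed between the siSIRT7 and siControl libraries. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, rose with log2 ratios of 2.04 without and 1.38 with irradiation (adjusted p = 8.1e-24). NOLC1, a nucleolar phosphoprotein of ribosome biogenesis, rose by 1.28 and 1.24 (adjusted p = 4.65e-32), and the aldo-keto reductases AKR1C1 (1.03 and 1.19) and AKR1C2 (1.10 and 1.14), which are near-identical in sequence, rose with them. Genes that fell included the ER-bound transcription factor CREB3L4 (-2.33 and -1.80), the mitochondrial isoleucyl-tRNA synthetase IARS2 (-2.14 and -1.63, adjusted p = 7.27e-57), the Dickkopf receptor KREMEN1 (-1.62 and -1.69), the zinc transporter SLC39A13 (-1.44 and -1.43), the ER membrane protein TMBIM6 (-1.44 and -1.40) and the lysosomal protease CTSS (-1.29 and -1.25). Also among the genes named by rule, MIR663A (2.29 and 1.45), HIC1 (1.34 and 1.34), ZNF765 (1.51 and 1.31), HIST1H2BD (1.28 and 1.11), ZNF267 (1.42 and 1.03), FAM222A (1.01 and 1.01), MED11 (1.03 and 0.99) and ZNF91 (0.96 and 1.10) rose. MIR663A is a miRNA entry of 93 bases, and the source of its reads was not tested. SCAF4 (-1.60 and -1.45), SAA2 (-1.37 and -1.45), SLC25A22 (-1.48 and -1.34), ZDHHC20 (-1.72 and -1.28) and ZYG11B (-1.40 and -1.22) fell.

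By the additive test 799 of the 11129 tested genes rose and 1198 fell with the knockdown. The counts of list members given below are to be read against these shares of all genes. Of the called genes 794 and 1194 went the same way in both pairs of libraries. They were called on both pairs together, so that agreement follows in large part from the selection. With the GC and length trend removed 1380 rose and 1250 fell, so which direction has more genes depends on that trend. Of the 799 and 1198 the median log2 changes were 0.41 and -0.47, and 86 and 241 of them differed by at least 1.5-fold in both pairs. Across 11129 genes the ratios of the pair without and the pair with irradiation, which share no library, correlated with r = 0.581 and rho = 0.544. The number of genes 2-fold or more lower in both pairs was 37, against 0.654 for independent draws, and 10 were higher in both, against 0.07. The heptamer TTCAGAA was picked in a search of 3' UTRs as the one most tied to lower ratios. It is held by 22 of those 37 genes, among them IARS2, KREMEN1, SLC39A13, TMBIM6, CTSS, SLC25A22, ZDHHC20, ZYG11B and MSMO1, a count that follows in part from that choice. Of the searched genes not called for the knockdown 23.9% hold it. DESeq2 called fewer, 256 that rose and 350 that fell, and all but 1 of these were also called by edgeR (255 and 350 shared). In the single pairs, 28 genes were 2-fold or more higher and 102 lower without irradiation, and 27 higher and 70 lower with it.

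**Figure D2:**
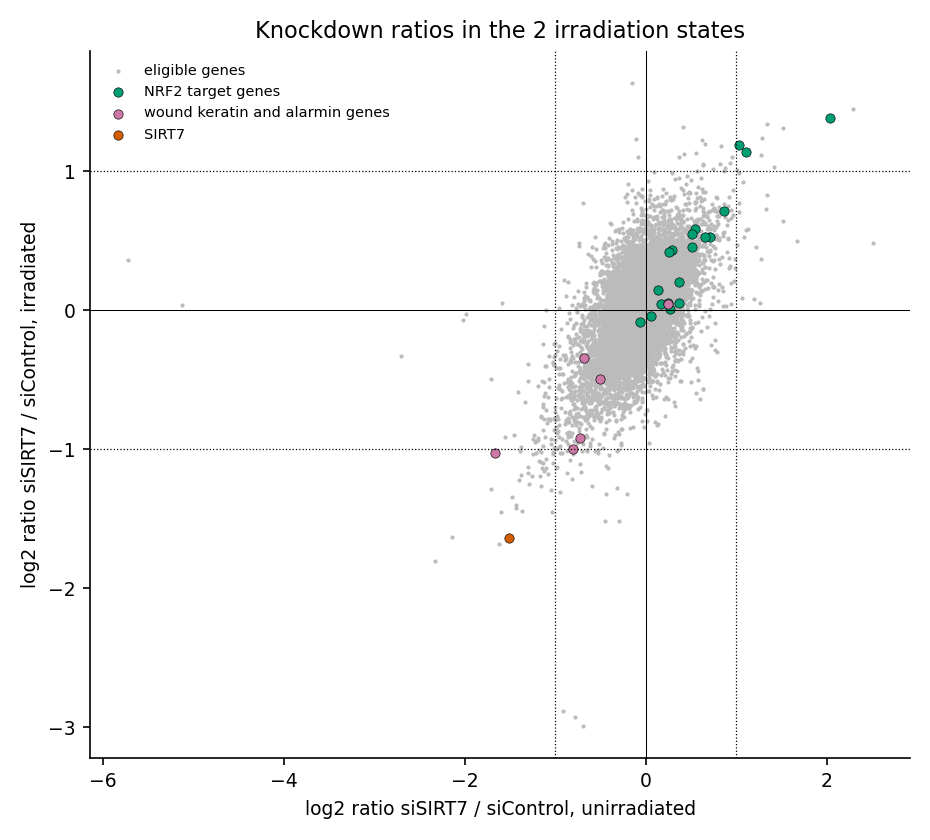
Each point is a gene, with its log2 ratio of siSIRT7 to siControl in unirradiated cells (x axis) and in irradiated cells (y axis), and dotted lines mark 2-fold. NRF2 target genes lie toward the upper right and wound keratin and alarmin genes toward the lower left, across 11129 genes with r = 0.581; the points of POSTN and HGF at the far left have 0 counts in 1 library, so their place depends on the prior count.

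Target genes of NRF2, the transcription factor of the antioxidant response, were higher with siSIRT7 as a group. Of 19 measured members 11 rose and none fell (12 adjusted over the list alone), among them HMOX1, the quinone reductase NQO1 (0.71 and 0.53), the glutamate-cysteine ligase subunit GCLM (0.54 and 0.58) and the cystine transporter SLC7A11 (0.51 and 0.55). The list's median was 0.37 without and 0.43 with irradiation, both at percentile 100 of the matched random lists. Genes of ATF4 and the unfolded protein response moved the same way: 10 of 17 rose (11 adjusted over the list alone), including DDIT3 (0.92 and 0.81), TRIB3 (0.91 and 0.51), DDIT4 (0.75 and 0.58) and ATF4 itself (0.57 and 0.46), with medians of 0.37 and 0.37. Among 18 cholesterol synthesis genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), with medians of 0.35 and 0.25. INSIG1 (0.86 and 0.54) and the sterol-regulated enzyme HMGCS1 (0.57 and 0.66) rose, and the sterol oxidase MSMO1 fell (-1.26 and -1.20). Of 28 genes of RNA polymerase I and ribosome biogenesis 12 rose and none fell (12 adjusted over the list alone), led by NOLC1, the polymerase subunit POLR1B (0.53 and 0.40) and the initiation factor RRN3 (0.47 and 0.37), with medians of 0.20 and 0.32. By DESeq2, 11 NRF2, 7 ATF4, 6 cholesterol and 6 ribosome biogenesis genes rose and 1 cholesterol gene fell.

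Wound keratin and alarmin genes were lower with siSIRT7 as a group, while some members of the inflammatory, suprabasal and basal lists were called. Of 6 measured wound keratin and alarmin genes 4 fell (5 adjusted over the list alone): the wound keratins KRT6A (-0.51 and -0.49) and KRT16 (-0.80 and -1.0), the alarmin subunit S100A9 (-1.66 and -1.03) and the antimicrobial lipocalin LCN2 (-0.73 and -0.92). The list's median was -0.71 in both pairs, at percentile 0. Of 15 inflammatory cytokine and NF-kB genes 4 fell, CCL2 (-0.17 and -0.73), TNFAIP3 (-0.55 and -0.40), ICAM1 (-0.33 and -0.48) and RELB (-0.33 and -0.51). Adjusted over the list alone the counts were 3 that rose and 5 that fell. The inflammatory medians of -0.15 and -0.11 lay inside the range of the random lists (percentiles 12.85 and 13.23). Among 6 suprabasal and cornified envelope genes FLG (-0.61 and -0.42), TGM1 (-0.35 and -0.75) and PPL (-0.16 and -0.40) fell (3 adjusted over the list alone). The median of that list was -0.04 at percentile 45.18 without irradiation. With irradiation it was -0.41 at percentile 0.19, which became -0.20 at percentile 3.41 once the GC and length trend was removed. Of 15 basal keratinocyte genes KRT15 alone passed the test (-0.72 and -0.45; 1 adjusted over the list alone). With that trend removed 2 suprabasal genes fell and 1 rose, and 5 basal genes rose and 2 fell. By DESeq2, 2 wound keratin and alarmin genes, 1 inflammatory gene and 1 basal gene fell, and 0 of the suprabasal list passed; its filter on mean counts left 3 wound, 3 inflammatory and 1 suprabasal gene without an adjusted p.

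Target genes of the DNA damage response, a list with CDKN1A, MDM2 and FAS, were called in both directions by edgeR with the knockdown. Of 23 measured members 6 fell and 2 rose, and the counts were the same adjusted over the list alone, while DESeq2 called 1 that fell and 0 that rose and gave 4 no adjusted p. The ubiquitin ligase gene MDM2 fell most (-1.55 and -0.91), SESN1 (-0.69 and -0.77), FAS (-0.95 and -0.25) and PIDD1 (-0.51 and -0.66) fell too, and the cell cycle inhibitor CDKN1A fell with ratios of -0.24 and -0.42. SESN2 (0.43 and 0.43), which is also on the ATF4 list, and AEN (0.40 and 0.24) rose. Among 25 type I interferon response genes RSAD2 (0.78 and 0.54), IFIT2 (0.26 and 0.44) and DDX58 (0.10 and 0.48) rose and BST2 (-0.71 and -1.17), IFI44 (-0.67 and -0.56) and IFI27 (-0.47 and -0.66) fell (3 and 4 adjusted over the list alone, 2 and 3 by DESeq2). The list's median was 0.10 without and -0.21 with irradiation.

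Genes of the translation and respiration machinery gave small shifts. Of 79 cytosolic ribosomal protein genes 6 rose, with ratios such as 0.37 and 0.27 for RPS27, and 0 rose adjusted over the list alone (5 by DESeq2). Among all 11129 tested genes 799 rose, so 6 of 79 is near the general share. The ribosomal protein medians were 0.19 and 0.17. Of 33 nuclear oxidative phosphorylation genes 5 rose, among them SDHB (0.38 and 0.38), and NDUFV1 fell (-0.26 and -0.32); the counts were the same adjusted over the list alone, DESeq2 called 2 that rose and 0 that fell, and the medians were 0.14 and 0.08. Ratios also moved with GC content of the transcript: rho across genes was 0.04 for the knockdown without and -0.46 with irradiation, and 0.50 and -0.34 for irradiation with siControl and with siSIRT7. Length had rho of -0.19, -0.04, -0.29 and -0.01 in that order. With those trends removed the ribosomal protein medians became 0.09 (percentile 52.7) and 0.07 (79.5) and those of oxidative phosphorylation 0.06 (50.2) and -0.03 (4.3). Of 13 mitochondrially encoded genes 4 fell with the knockdown (5 adjusted over the list alone, 1 by DESeq2), ND4 (-0.49 and -0.15), ND4L (-0.43 and -0.10), ATP6 (-0.54 and -0.28) and ATP8 (-1.12 and -0.11), with medians of -0.24 and -0.02. The irradiated median lay at percentile 32.96, so these calls rest mainly on the unirradiated pair. The 13 genes had no GC-corrected value, since their symbols did not match the transcript set.

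**Figure D3:**
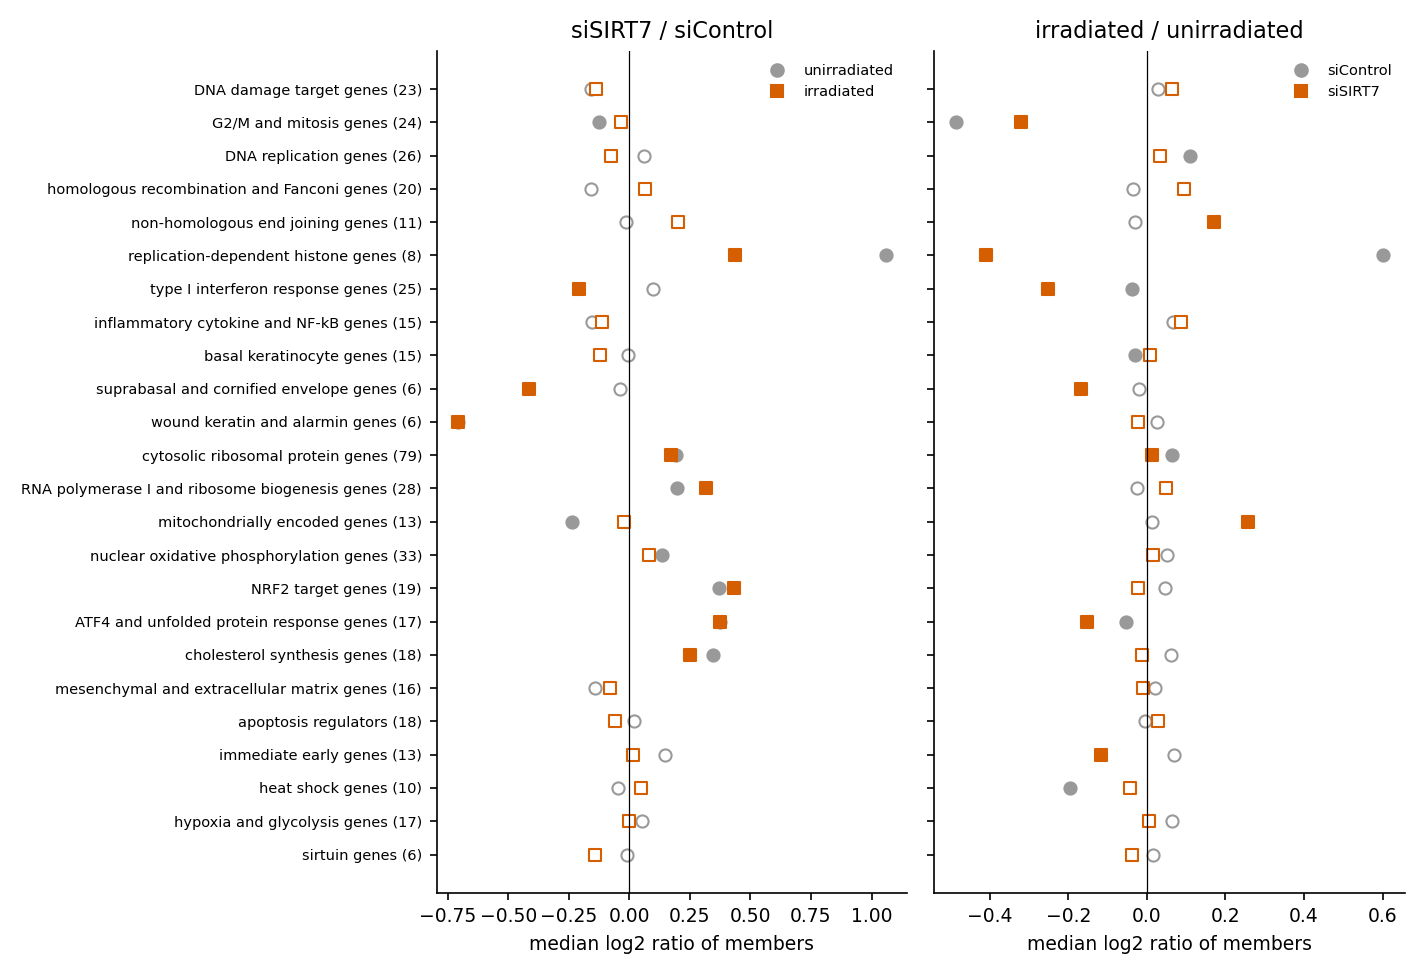
Median log2 ratio (x axis) of each gene list, with the number of measured members in brackets, for siSIRT7 against siControl in the left panel and for irradiated against unirradiated cells in the right panel. Filled symbols lie outside the central 95% of matched random lists, which held for 46 of 125 list comparisons. Independent comparisons would give 6.2, but these share libraries and some members, so 6.2 is no exact expectation. The counts include the list of other skin cell markers and the differences of the irradiation effect, both not drawn. G2/M genes have medians of -0.49 and -0.32 in the right panel.

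The next question was what irradiation did. Of 24 G2/M and mitosis genes 9 fell and none rose (22 adjusted over the list alone, 6 by DESeq2), and the medians were -0.49 with siControl and -0.32 with siSIRT7, both at percentile 0. The mitotic kinases AURKA (-1.11 and -0.88, adjusted p = 2.24e-18) and PLK1 (-0.64 and -0.79, adjusted p = 7.94e-10) fell, with the kinesins KIF20A (-0.69 and -0.93) and CENPE (-0.93 and -0.68), the kinetochore protein CENPF (-0.62 and -0.78) and cyclin B1, CCNB1 (-0.58 and -0.56). Outside that list the helicase PIF1 fell most (-1.37 and -1.70, adjusted p = 2.24e-18), and GTSE1 (-0.71 and -0.80), FAM83D (-0.68 and -0.80), PSRC1 (-0.68 and -0.88), SGO2 (-0.82 and -0.68), DEPDC1 (-0.99 and -0.63), KIF14 (-1.04 and -0.59) and the polyadenylated histone gene HIST2H2BE (-0.72 and -0.87) fell as well. AURKA and KIF20A also fell with the knockdown, as did KIF23 (-0.52 and -0.06), the 3 members of the list that did (3 adjusted over the list alone, 2 by DESeq2). Of 10 heat shock genes the near-identical HSPA1A (-0.34 and -0.54) and HSPA1B (-0.31 and -0.55) fell with irradiation (3 adjusted over the list alone, 1 by DESeq2).

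RPPH1, the 7SL RNAs and 3 histone H4 genes rose with irradiation, while RMRP, another small noncoding RNA, was called as falling. RPPH1, the RNA of ribonuclease P (chromosome 14, 20811230 to 20811570, hg19), rose from 457.3 to 1389 CPM with siControl and from 302.5 to 1144 CPM with siSIRT7 (log2 1.60 and 1.92, adjusted p = 5.73e-50). The 7SL RNAs of the signal recognition particle rose alike: RN7SL1 by 1.42 and 1.15, RN7SL2 by 1.51 and 1.21 and the copy RN7SL4P by 2.49 and 1.53, genes with near-identical sequence. Signal recognition particle RNA took 0.164% and 0.141% of the counts in unirradiated siControl and siSIRT7 cells and 0.445% and 0.319% in irradiated ones. RN7SK, a small nuclear RNA and regulator of transcription elongation, rose (0.99 and 0.35), and of 8 measured replication-dependent histone genes HIST1H4D (2.21 and 3.13), HIST1H4E (1.90 and 1.21) and HIST1H4C (1.11 and 1.21) rose (3 adjusted over the list alone, 2 by DESeq2). HIST1H4D rests on 10, 8, 53 and 88 counts. The other histone genes of the list behaved otherwise. HIST1H1E (0.90 and 0.42), HIST1H2AE (1.22 and 0.45), HIST1H2AM (1.26 and 0.05), HIST1H3D (1.51 and 0.64) and HIST1H3H (1.67 and 0.50) rose with the knockdown by edgeR (5 adjusted over the list alone). DESeq2 called 0, and its filter on mean counts left 7 of the 8 without an adjusted p. Of the list 4 genes were 2-fold or more higher with siSIRT7 without irradiation and 0 with it, so these calls rest mainly on the unirradiated pair. The list's median irradiation ratio was 0.60 with siControl and -0.41 with siSIRT7.

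Irradiation changed no DNA damage target gene past the threshold: 0 of 23 by edgeR (0 adjusted over the list alone), 1 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. The list's medians were 0.03 with siControl and 0.06 with siSIRT7, and the latter became 0.10 at percentile 99 with the GC and length trend removed. CDKN1A had ratios of 0.24 and 0.06 and MDM2 of -0.30 and 0.34. In all, 19 genes rose and 35 fell with irradiation, with DESeq2 calling 7 and 13. Of the 19 and 35, 18 and 34 went in the same direction in both pairs, which follows in large part from calling them on both pairs together. Across 11129 genes the irradiation ratios of the pair with siControl and the pair with siSIRT7 correlated with r = 0.035 and rho = -0.102, or r = 0.141 with the GC and length trend removed. In the single pairs 11 genes were 2-fold or more higher and 3 lower with siControl, and 16 higher and 2 lower with siSIRT7. The number higher in both was 8, against 0.018 for independent draws. It was 3 among protein-coding genes (against 0.006) and 2 with the GC and length trend removed (against 0.005). The 8 include the near-identical RN7SL1, RN7SL2 and RN7SL4P, which may be 1 signal, so they are not independent draws. Named by rule without passing the test were NR4A1 (0.72 and 0.94, adjusted p = 0.195), COL1A1 (0.78 and 0.71, adjusted p = 0.214) and FOS (0.61 and 0.66, adjusted p = 0.752).

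**Figure D4:**
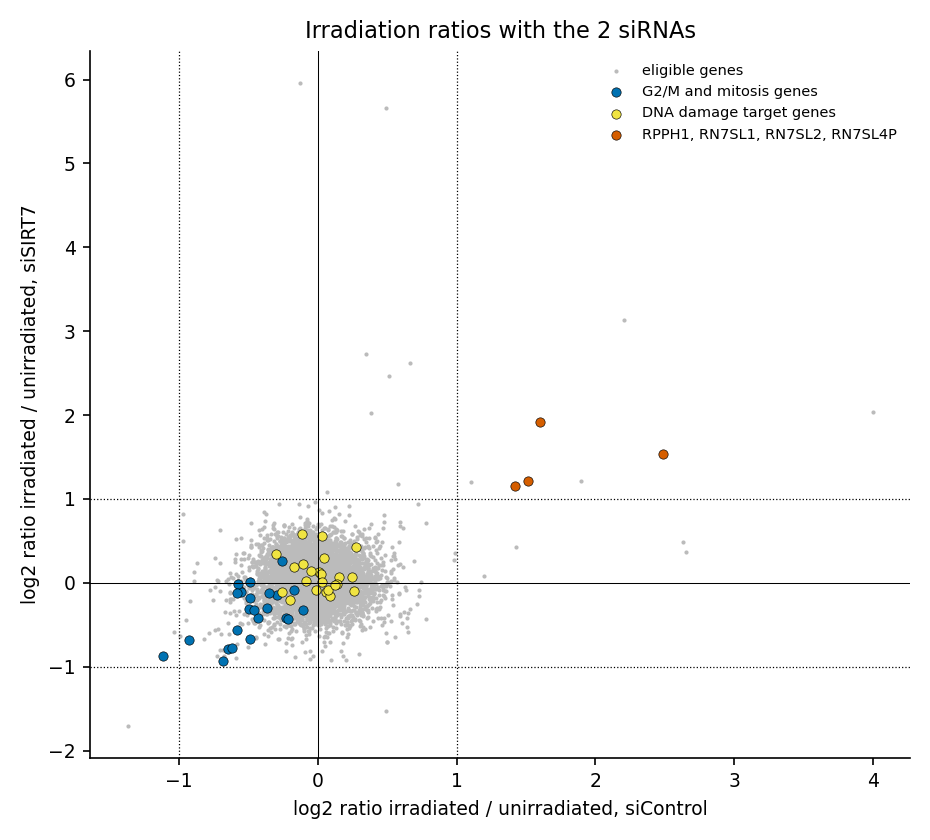
Each point is a gene, with its log2 ratio of irradiated to unirradiated cells with siControl (x axis) and with siSIRT7 (y axis), and dotted lines mark 2-fold. G2/M genes lie toward the lower left, DNA damage target genes around 0 (medians 0.03 and 0.06) and RPPH1 and the 7SL RNAs beyond 2-fold on both axes; the points of POSTN and HGF near the top have 0 counts in 1 library, so their place depends on the prior count.

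Some calls rest on 1 library. Several mesenchymal genes, picked out after their values were seen, had their fewest counts in the unirradiated siSIRT7 library, while the mesenchymal list as a whole had a median log2 ratio of -0.14 in the unirradiated pair (percentile 6.47). The intermediate filament gene VIM had 319, 39, 399 and 282 counts in unirradiated siControl, unirradiated siSIRT7, irradiated siControl and irradiated siSIRT7 cells. The matrix genes COL1A2 (102, 27, 131 and 121), COL3A1 (134, 26, 188 and 159) and POSTN (113, 0, 101 and 116) were lowest in that library too. With the floor of 3 counts set in the library at 0, POSTN was 31.3-fold lower with siSIRT7 without irradiation. It was 36.9-fold higher after irradiation of siSIRT7 cells, and the growth factor HGF, with 0 and 94 counts in those cells, 29.9-fold higher. The counting intervals allow smaller folds, with limits at log2 ratios of -4.65 and 4.88 for POSTN and 4.58 for HGF. These genes and the collagens COL6A3 (0.66 and 2.62) and COL6A2 (0.58 and 1.18) are among the 19 genes called as rising with irradiation. Of 16 mesenchymal and extracellular matrix genes 5 fell and 1 rose with the knockdown (6 and 2 adjusted over the list alone, 1 and 1 by DESeq2, which gave 3 no adjusted p). VIM and POSTN among them rest on that library, while FN1 (-0.60 and -0.67), COL4A2 (-0.27 and -0.38) and TAGLN (-0.24 and -0.52) fell in both pairs. With irradiation 2 rose, VIM and POSTN (2 adjusted over the list alone, 0 by DESeq2). The list's median was -0.14 and -0.08 for the knockdown and stayed at -0.14 with POSTN at its bound. Of 3 measured markers of other skin cell types COL1A1 (-0.83 and -0.90) and COL3A1 (-2.03 and -0.07) fell with the knockdown (3 adjusted over the list alone; DESeq2 gave none of the 3 an adjusted p) and COL1A2 (0.38 and 2.02) and COL3A1 (0.51 and 2.46) rose with irradiation (3 adjusted over the list alone, 0 by DESeq2).

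The imprinted growth genes IGF2 and H19 stood out in the irradiated siControl library. H19, a long noncoding RNA, had 11, 4, 204 and 23 counts in the order above and IGF2 16, 7, 108 and 11. The readthrough gene INS-IGF2 overlaps IGF2 (both start at 2150342 on chromosome 11, hg19) and had 15, 7, 104 and 10. All 3 were called as rising with irradiation and falling with the knockdown. RMRP, the RNA of ribonuclease MRP, had 159, 760, 220 and 275 counts, was called as rising with the knockdown (2.51 and 0.49) and as falling with irradiation (0.49 and -1.53), and rests on the unirradiated siSIRT7 library. The additive test cannot be repeated without any of the libraries, since no residual degree of freedom would remain.

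The last question was whether irradiation acted differently in siSIRT7 cells, which these 4 libraries give as values without a test. The difference of the 2 irradiation ratios was 2-fold or more higher in siSIRT7 cells for 27 genes and lower for 21 of 11129. Apart from POSTN and HGF the highest were VIM (2.38), COL6A3 (1.96), COL3A1 (1.95) and MIR6087 (1.79), and the lowest INS-IGF2 (-2.29), IGF2 (-2.15), RMRP (-2.02), H19 (-1.97), the cytokine signalling inhibitor SOCS1 (-1.24) and ANKRD65 (-1.22). MIR6087 is a miRNA entry of 49 bases with 14241 to 39409 counts, and the source of its reads was not tested. Type I interferon response genes had a median difference of -0.24 and mitochondrially encoded genes of 0.26, at percentiles 0 and 100. The irradiation ratio of the interferon list was -0.04 with siControl and -0.25 with siSIRT7, and 0 of its 25 members passed the additive irradiation test by edgeR (2 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom). The mitochondrial ratios were 0.01 and 0.26, and ATP8 (0.07 and 1.08) rose with irradiation (1 adjusted over the list alone, 0 by DESeq2), with 1024 counts in the unirradiated siSIRT7 library against 2275 to 2761 in the others. The G2/M list had a median difference of 0.14 at percentile 99.8, which became -0.01 at percentile 55.8 once the GC and length trend was removed.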

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

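Chosen only after the results were seen were the tests of a common knockdown effect on mesenchymal genes and of reads moving between 7SL copies (chosen after an earlier test on RPPH1, smaller ratio 1.603, was set aside as uninformative), the counts of shared genes after thinning and GC correction, the repeat of the fibroblast list without the GC trend, and the minimum of 10 RNAs for the test of non-polyadenylated RNA.

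Among the genes named by rule, 6 went opposite ways in 2 pairs of libraries, with counting intervals that excluded 0 in each; the differences were not tested. The irradiation ratios with siControl and with siSIRT7 were 0.424 and -0.235 for HMOX1, -0.113 and 0.398 for IARS2, -0.195 and 0.236 for ZDHHC20, and 0.492 and -1.528 for RMRP. They were -0.972 and 0.822 for MIR6087 and 0.65 and -0.586 for SOCS1. The knockdown ratios without and with irradiation were -0.157 and 1.636 for MIR6087 and 0.596 and -0.64 for SOCS1.

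The first pattern is the set of 37 genes 2-fold or more lower in both siSIRT7 libraries. After all libraries were thinned to 16829544 counts 37 genes were 2-fold lower in both, 35 of them shared with the original 37. The largest total before thinning was 19745170, so thinning took few reads and the count could hardly have changed. It decides nothing about fewer reads as a cause. After removal of the trend on GC content and length 35 were 2-fold lower in both, 28 of them shared (33 and 27 with the trend removed from each library). That argues against GC content or length as the whole cause. A candidate explanation is off-target silencing through the siRNA seed: of all heptamers in 3' UTRs, TTCAGAA marked the lowest ratios in each pair, which share no library, with z of -13.42 without and -12.46 with irradiation against -5.13 and -5.06 as the most extreme of 200 permutations, and no heptamer passed that bound among lower ratios of the irradiation pairs (-3.64 and -3.91). The overlapping heptamer TCAGAAA came next in both pairs, with z of -10.95 and -10.68. The effect of TTCAGAA across genes is small, an adjusted difference of -0.10 and -0.086 (medians of -0.122 and -0.007 with the heptamer, -0.003 and 0.004 without). Heptamers tied to higher ratios passed their bounds too, by less (5.78 against 4.91 and 5.76 against 4.61), so passing alone is not particular to a seed. TTCAGAA stands in 22 of the 37, among them IARS2, KREMEN1, TMBIM6 and MSMO1, which restates its choice on these same ratios and is no further test. Of 1139 searched genes that fell 740 have no site. The share with it was 35.0%, against 23.7% of uncalled genes matched on UTR length and 16.3% of genes that rose. Those shares also follow in part from that choice. The siRNA sequence is not given in the sources used here, and the 1 copy in the SIRT7 transcript is shared by 18.8% of 896 transcripts of similar length. The prediction written beforehand for a seed effect was met. TTCAGAA led in both pairs beyond the permutations and occurs in the SIRT7 transcript. Without the siRNA sequence the size of an off-target part is not known, and an off-target part and an effect of SIRT7 loss both stay open.

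The second pattern is the low level of COL1A2, COL3A1, POSTN and VIM in the unirradiated siSIRT7 library, the members of the mesenchymal and other skin cell lists that were 2-fold or more lower in that pair. For these 4 genes alone, a median ratio of -0.01 in the irradiated pair, which shares no library with the pair they were chosen in, argues against a knockdown effect of like size in both irradiation states; FN1, COL4A2, TAGLN and COL1A1 fell in both pairs. A separate list of 23 fibroblast genes was higher in the other 3 libraries by a median of 0.296, at percentile 99.99 of matched lists (99.98 without the GC trend), which is consistent with RNA of a mesenchymal cell type that is missing from this library. Its shift is far below that of the 4 genes, and it is uneven: COL5A2 had 8 counts against 60 to 65, FBN1 64 against 59 to 79 and the abundant EFEMP1 2292 against 2935 to 3399. HaCaT cells express many of these genes, the list also lay in the opposite tail for irradiated siControl (median -0.271), and a knockdown effect that irradiation removes stays open, so no source can be named.

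The third pattern is the rise of RPPH1 and the 7SL RNAs in both irradiated libraries. The counts summed over all 140 entries of 7SL and its copies were higher in both, with a smaller ratio of 1.182, which argues against reads moving between copies, although the calls of the near-identical 7SL genes may be 1 signal and RPPH1 is outside this test. A higher share of non-polyadenylated RNA in the irradiated libraries may contribute and cannot be told apart from an effect of irradiation. The other such RNAs had medians of -0.008 with siControl and 0.014 with siSIRT7. Only 5 were eligible and they went both ways, from RN7SK (0.99 and 0.35) to RMRP (0.49 and -1.53). The bound written for this test of a higher share would have counted 0.014 against it, had the minimum of 10 RNAs not been added. Replication-dependent histone genes were not part of the test, and their list medians went both ways too (0.60 with siControl and -0.41 with siSIRT7). An effect of irradiation on RPPH1 and the 7SL RNAs stays open.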

How the results depend on the processing

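The alternatives with the GC and length trend removed, with protein-coding genes only, and with floors of 1 and 20 CPM in the additive test were chosen after seeing the data. Of the counts and correlations under all alternatives, 80 stayed within 1.5 times the reported count or within the interval of the correlation, 63 moved further and 1 reversed. Of the list medians 692 kept their side of the central 95%, 21 fell back inside it, 17 left it and 5 of those outside it reversed. Medians inside it changed sign in 46 of 471 comparisons, from at most 0.12 to at most 0.211 in size, all counted among the 692. Of the ratios of named genes 453 kept within their counting interval and 12 moved.

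The number of genes 2-fold or more higher and lower depends on the floor, since genes near it have few counts. With a floor of 1 CPM the counts were 152 and 281 for the knockdown without irradiation, 133 and 223 with it, 86 and 77 for irradiation with siControl, 157 and 103 with siSIRT7, and 306 and 248 for the difference. A floor of 20 gave 11 and 52, 8 and 35, 4 higher, 5 higher, and 6 and 1 in that order, and no floor gave 1422 and 1436, 1534 and 1142, 763 and 916, 1735 and 1498, and 2513 and 2081. With TPM they were 78 higher, 48 and 107, 48 and 41, 39 and 54, and 64 and 96. Without the GC and length trend 13 were higher with the knockdown after irradiation, 4 with irradiation and siControl, 10 with irradiation and siSIRT7, and 14 for the difference. Protein-coding genes alone gave 5 higher with irradiation and siControl and 1 lower with irradiation and siSIRT7. For TPM and the GC trend the cause was not tested.

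The correlation of the knockdown pairs was 0.594 with a prior count of 10, 0.413 with a floor of 1, 0.653 with a floor of 20, 0.146 with no floor, 0.452 with TPM and 0.659 without the GC trend. That of the irradiation pairs was 0.0837 with a floor of 1, -0.0281 with a floor of 20, 0.0003 with TPM, 0.141 without the GC trend and 0.0044 over protein-coding genes; the cause was not tested. DESeq2 called 256 genes that rose and 350 that fell with the knockdown and 7 and 13 with irradiation. Without the GC trend 1380 rose and 1250 fell with the knockdown (664 of the 799 and 957 of the 1198 among them), more up than down, and 64 fell with irradiation (33 of the 35 among them). Irradiation raised 40 genes with no floor, 34 with the filterByExpr minimum, 33 with a floor of 1 and 7 with a floor of 20, where fewer genes are tested. The reversed medians among those outside the central 95% were the difference for end joining genes with a floor of 20 (-0.10), the ribosomal protein median for irradiation with siSIRT7 under median-of-ratios scaling (-0.012) and without the GC trend (-0.022), that with siControl without the GC trend (-0.004), and the G2/M difference without the GC trend (-0.011); the cause was not tested.

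Each condition has 1 library, so leaving out a library leaves no residual degree of freedom, and variation between cultures was not measured. The mitochondrially encoded list could not be given a value with the GC trend removed. Ratios of POSTN and HGF depend on the prior count, and histone and imprinted genes near the floor rest on few counts.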

Other observations

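The removal of the GC trend, the genes named within the lists, and MKI67, CENPA, NEAT1 and H1F0 outside them were chosen after their values were seen; the counts of list members by the other tests were planned.

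Several smaller groups had members called for the knockdown. Of all 11129 tested genes 799 rose and 1198 fell, so a few calls do not set a list apart. Among 18 apoptosis regulators the BH3-only gene PMAIP1 (0.63 without and 0.62 with irradiation) and the caspase inhibitor XIAP (0.19 and 0.72) rose (2 adjusted over the list alone, 1 by DESeq2). Of 13 immediate early genes IER2 (0.66 and 0.45), KLF4 (0.50 and 0.14) and MYC (0.48 and 0.34) rose and NR4A1 (-0.83 and -0.62) fell, 3 and 1 also adjusted over the list alone and 2 and 0 by DESeq2, which gave 2 members no adjusted p. Of 17 hypoxia and glycolysis genes the vasoactive peptide gene ADM (0.72 and 0.52) and the hexokinase HK2 (0.26 and 0.41) rose, and PFKFB3 (-0.66 and -0.65) and PDK1 (-0.57 and -0.39), regulators of glycolysis and pyruvate use, fell (2 and 2 adjusted over the list alone, 1 and 1 by DESeq2). Among 10 heat shock genes HSPD1 (-0.01 and 0.59) rose and BAG3 (-0.27 and -0.46) fell (1 and 1 adjusted over the list alone, 0 by DESeq2). The proliferation marker MKI67 fell with the knockdown (-0.75 and -0.74) and with irradiation (-0.43 and -0.42), and the centromeric histone gene CENPA did as well (-1.05 and -0.96; -0.70 and -0.61).

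Few genes of DNA replication and repair passed the test for the knockdown. Of 26 DNA replication genes the helicase subunit MCM6 (-0.47 and -0.27) and the ligase LIG1 (-0.22 and -0.46) fell with the knockdown (2 adjusted over the list alone, 0 by DESeq2). Of 20 homologous recombination and Fanconi genes BRCA2 rose (0.74 and 0.17), and of 11 end joining genes NHEJ1 rose (0.56 and 0.29), with 0 in each list adjusted over the list alone and by DESeq2, which gave 1 and 2 members no adjusted p. In 19 of the 25 lists 0 members passed the additive irradiation test by edgeR: over their 395 memberships 9 were higher and 9 lower at an unadjusted p under 0.05, 6 passed adjusted over the list alone, 0 passed by DESeq2 and by limma-voom, and 3 passed with the GC trend removed. The long noncoding RNA NEAT1 (-0.57 with siControl and -0.34 with siSIRT7) and the linker histone gene H1F0 (-0.39 and -0.61) fell with irradiation, and H1F0 also fell with the knockdown (-0.69 and -0.92).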
